A study of Mus musculus with 6 samples.

How the data were processed

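The series measured total RNA of KLS cells, the bone marrow fraction that carries Kit and Sca-1 and lacks mature lineage markers and that holds the haematopoietic stem cells and multipotent progenitors. There were 3 arrays from wild-type mice and 3 from Dnmt3a+/- mice, which carry 1 disrupted copy of the DNA methyltransferase gene Dnmt3a. The genotype and the replicate number of each array were taken from the labels. Per the labels' protocols, RNA was extracted with TRIzol, 20 ng of it was amplified as whole-transcript cDNA, and the product was labelled with biotin, so each array reads 1 sample in 1 colour. The labels do not say whether arrays of a genotype came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

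The authors deposited a table of normalized intensity values, 1 per probe set and array. Per the submitters' processing notes, the values were made with RMA, which corrects background, quantile-normalizes and summarises probes, in Partek. The versions and settings are not given in the sources used here. RMA usually gives log2 values, but the deposited values ran from 1.84 to 22239 with array medians from 59.8 to 61.6, so they were on a linear scale and log2 was taken before any test. No pseudocount was needed. The similar quantiles show that the arrays were brought to nearly one distribution, so a change shared by most genes cannot be seen. The table held 1256831 probe sets, and every column belonged to 1 of the 6 arrays. Arrays give no counting depth, and their number limits the precision.

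Probe sets were named through the platform's annotation table, which can be old. Of all probe sets, 318760 had 1 gene symbol (25.4%), 6684 had several and 931387 had none listed. Only those with 1 symbol were named. Of the 22296 platform symbols, 18006 were current in the RefSeq gene table of assembly GRCm38.p6, 4227 were updated because they were an older name of exactly 1 gene, and 63 were kept as given. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed. The RefSeq table served for names and for which genes lie near Dnmt3a.

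A gene's value was the mean log2 value of its named probe sets whose mean over all arrays lay above the median of all probe-set means (log2 5.89). This kept 628415 probe sets, 221209 of them named, and gave 20059 genes with a median of 8 probe sets each. A total of 2090 genes rested on 1 probe set. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with no covariate), and p-values were adjusted by the Benjamini-Hochberg method. The same fit was run on the 628415 single probe sets and on every probe set named Dnmt3a. The plan had made the Dnmt3a probe-set test depend on known positions or a known order. Neither was known, and the test was run nonetheless. Differences are Dnmt3a+/- minus wild-type on the log2 scale with the fit's standard error (SE). Single values were also compared with an exact two-sided permutation test, which with 3 against 3 arrays cannot give a p under 0.1. Genes were also counted by size alone: all arrays of one genotype above all of the other, and means at least 1.5-fold apart. Chance leaves 10% of genes non-overlapping in this way.

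Before the data were examined, 27 gene lists were written down, together with the tests, the filters, the alternatives and the rule for the genes named in the text. They cover DNA methylation, stem and progenitor cells, lineages that the sort should remove, cell cycle, stress, interferon response, chromatin, imprinting, germ cells, ribosomes and respiration. Of these, 26 were tested with camera (limma, two-sided, preset inter-gene correlation 0.01, adjusted over the lists), and the sex-linked genes are given as values. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera uses the few residual degrees of freedom of the arrays, and with a preset one those of the genes. The estimated version therefore has less power. Camera compares a list with all other genes, while fry asks whether its genes move, on balance, one way. A list median was also placed among the medians of 10000 random lists matched on mean level, a check added after the data were examined. Lsh in the DNA methylation list is an older name of Hells, which was counted once. The rule named Dnmt3a, Dnmt1, Dnmt3b and Tet2, every gene past adjusted p 0.05, the 12 largest positive and 12 largest negative differences among genes with an unadjusted p under 0.01 and non-overlapping genotypes (predicted genes and olfactory or vomeronasal receptors were counted instead), the 3 members of each list with the smallest p, and the sex-linked genes. Further members of called lists are named as examples and were chosen after their values were seen.

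The gene fit was tested on simulated data made from the real means and spreads of the 20059 genes, in 20 runs with 200 genes changed in each. At adjusted p 0.05 it recovered 20.1% of genes changed 1.5-fold, 64.1% of those changed 2-fold and 92.7% of those changed 4-fold, with a median of 4 false calls. A list shifted by -0.3 was called in 100% of runs with the preset correlation and in 75% with an estimated one, with independent genes. Alternatives were other filters on dim probe sets (none, or the 75th percentile), the median of probe sets, a second quantile normalization, cyclic loess, a variance trend with robust estimation, array weights, the replicate number as a block, and leaving out each array in turn.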

Results

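The data were whole-transcript array profiles of sorted KLS bone marrow cells from 3 wild-type and 3 Dnmt3a+/- samples. By its title, the study concerns how the loss of 1 copy of Dnmt3a prepares blood-forming cells for myeloid malignancy. The comparison of the genotypes asks which genes differ in these stem and progenitor cells when only 1 intact copy of Dnmt3a remains. After the filter on dim probe sets, 20059 genes were measured on every array.

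Dnmt3a, the targeted gene and one of the enzymes that place new DNA methylation, was lower on every Dnmt3a+/- array than on any wild-type array. Its gene value was 8.57 ± 0.11 (SD, n = 3) in wild-type and 8.26 ± 0.10 (SD, n = 3) in Dnmt3a+/- cells. The log2 difference of -0.31 (SE 0.12, 95% confidence interval -0.57 to -0.04) corresponds to a fold of 0.809. The single arrays read 8.51, 8.70 and 8.50 in wild-type and 8.38, 8.20 and 8.20 in Dnmt3a+/- cells. The exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. Among all genes the difference did not pass (limma, adjusted p = 0.631), and its size depended on the scaling, at -0.17 after cyclic loess.

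The 37 probe sets named Dnmt3a had differences from -1.04 to 0.66. In 28 of them the Dnmt3a+/- mean was lower, and in 10 the genotypes did not overlap, each time with Dnmt3a+/- below wild-type, where chance would leave 10%. Probe set 5459494 had the lowest difference, -1.04 (SE 0.30), followed by 5421207 at -0.97 (SE 0.29). Bright probe sets at the other end, such as 5267431 at 0.18 (SE 0.23) and 4990333 at 0.08 (SE 0.33), lay near 0. No probe set passed when adjusted over the 37 alone (smallest adjusted p = 0.158, limma), and 7 had an unadjusted p under 0.05. With a variance trend and robust estimation 4 of them passed, all lower. Their positions in the gene were not used here, so which of them lie in the disrupted part is not known.

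**Figure D1:**
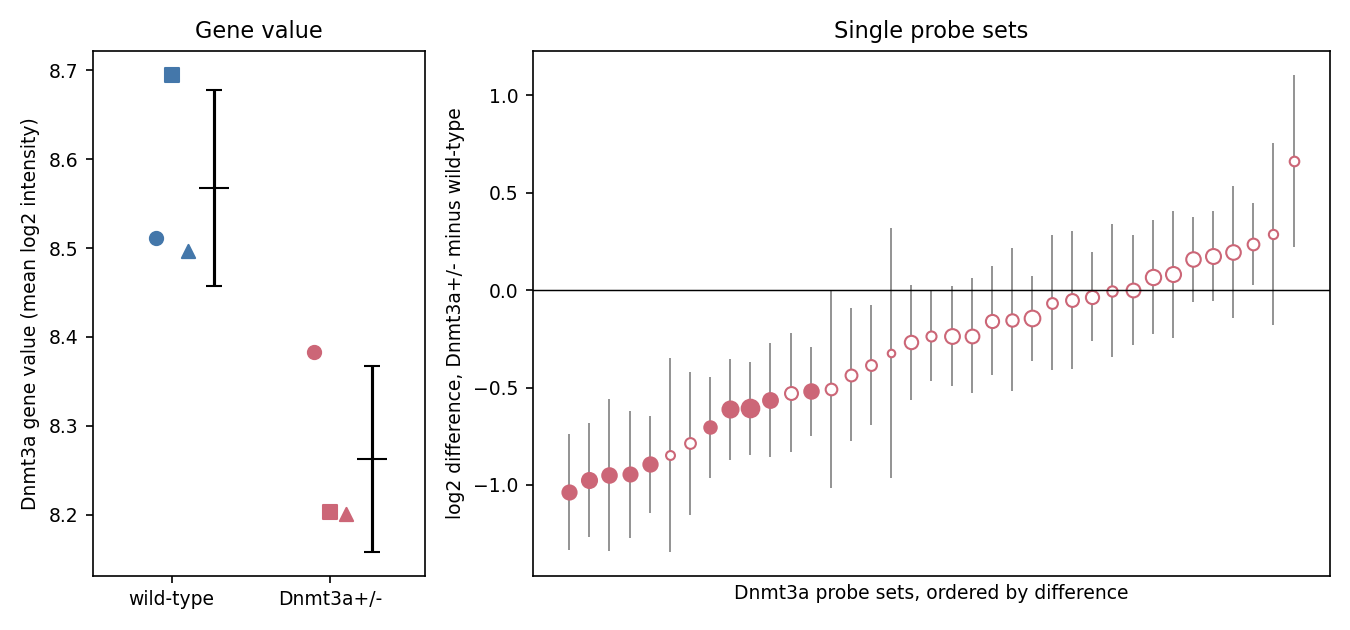
Left, the Dnmt3a gene value of each array (circle, square and triangle for replicates 1, 2 and 3) with the mean and SD of each genotype (n = 3), in log2 intensity. Right, the log2 difference of each of the 37 Dnmt3a probe sets with its SE, filled where the genotypes do not overlap and drawn larger for brighter probe sets; the differences run from -1.04 to 0.66.

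The arrays did not separate by genotype. Pearson correlations across genes were 0.948 to 0.964 between wild-type arrays, 0.902 to 0.954 between Dnmt3a+/- arrays and 0.897 to 0.962 between genotypes, so no pair was a duplicate. Dnmt3a+/- replicate 2 stood apart, with a mean correlation of 0.904 with the others, and the first principal component (41.1% of the variance) set it against the rest. On that array the dimmest 10% of genes had a median difference of 0.15 from the wild-type mean, and the brightest 10% one of -0.27. Across genes, the difference between genotypes correlated negatively with the level (Spearman -0.369, and -0.22 without Dnmt3a+/- replicate 2, over genes, which are not independent replicates). Without the filter on dim probe sets, every array carried the Y-linked transcripts Eif2s3y (8.40 to 8.63) and Kdm5d (7.23 to 7.54). Uty read 6.11 to 7.25. Xist, the RNA of the inactive X, was dim on all of them (4.54 to 5.02, where the median level of olfactory receptor genes was 4.32). Its antisense Tsix read 5.18 to 6.45. With the filter, Tsix was 6.90 ± 0.11 in wild-type and 7.55 ± 0.35 in Dnmt3a+/- cells (SD), and passed adjusted over the sex-linked list alone (adjusted p = 0.0333, limma) but not over all genes (adjusted p = 0.631).

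**Figure D2:**
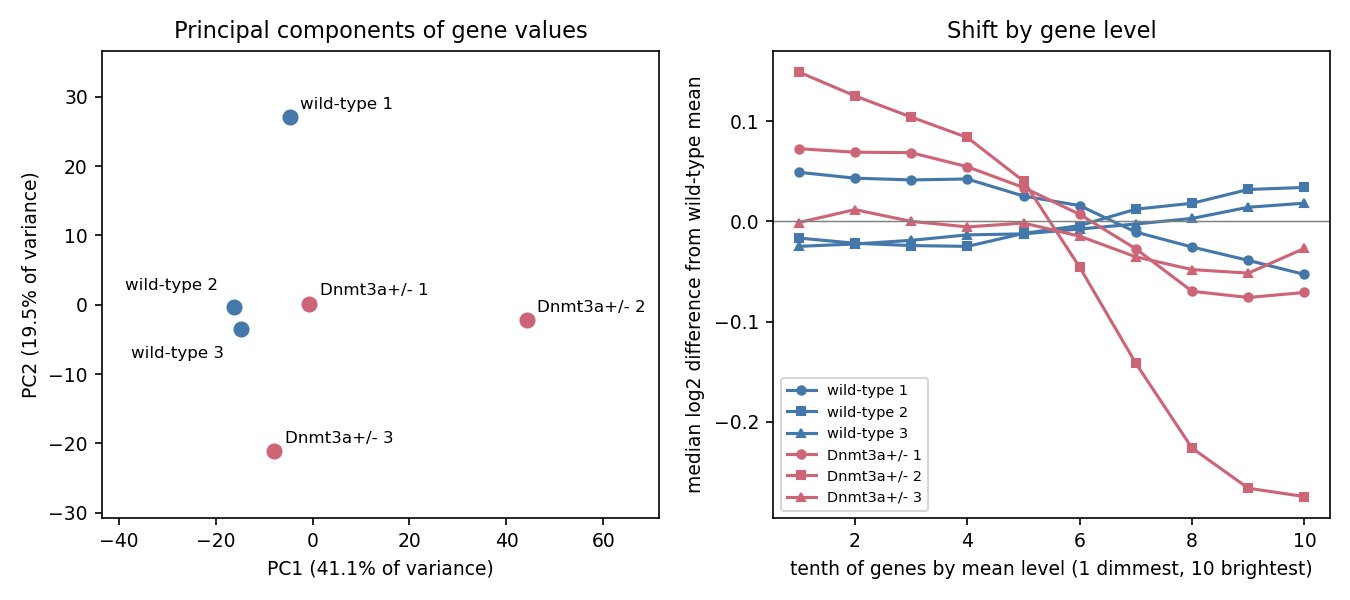
Left, the first and second principal components of the gene values (41.1% and 19.5% of the variance), 1 point per array; Dnmt3a+/- replicate 2 lies far from the rest on the first. Right, the median log2 difference of each array from the wild-type mean, in 10 equal groups of genes ordered by mean level; Dnmt3a+/- replicate 2 runs from 0.15 in the dimmest to -0.27 in the brightest group.

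No single gene differed between the genotypes after adjustment (limma, 0 of 20059 genes at adjusted p 0.05, smallest adjusted p = 0.535). At unadjusted p under 0.05 there were 1502 genes, where chance gives 1003. At unadjusted p under 0.01 there were 260 (118 higher and 142 lower in Dnmt3a+/- cells), where chance gives 200.6. In the simulated runs a mean of 215 unchanged genes per run had such a p, so the excess is small. The genotypes did not overlap for 15.8% of genes, where chance gives 10%, and 174 of these were at least 1.5-fold apart, 102 higher and 72 lower. Without wild-type replicate 2 or 3 the 260 genes became 128 or 154. The count of genes apart by 1.5-fold was 269 to 473 without any single array other than Dnmt3a+/- replicate 2, since fewer arrays overlap less often. Among single probe sets, 0 of 628415 passed (limma), and 39000 had an unadjusted p under 0.05, where chance gives 31420.8.

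The genes with the largest differences are given as values, since none passed. Slc15a2, a peptide transporter, was highest in Dnmt3a+/- cells relative to wild-type, with a log2 difference of 1.70 (SE 0.43) with SDs of 0.90 in wild-type and 0.47 in Dnmt3a+/- cells (n = 3). Retnlg, a resistin-like protein of neutrophils, differed by 0.98 (SE 0.22), from 8.39 ± 0.21 to 9.37 ± 0.43 (SD, n = 3). The log2 differences of the other genes on this side were 1.34 for Orly, 1.28 for Slxl1, 1.22 for the steroid enzyme gene Hsd3b6, 1.19 for the kallikrein Klk1b22, 1.14 for the helicase Ddx43, 0.97 for Lkaaear1, 0.95 for the prolactin family gene Prl5a1, 0.95 for the hair keratin-associated Krtap13, 0.94 for the epidermal Sprr2b and 0.91 for Aym1. Of these 12 genes, 9 lay below the median gene level and 6 rested on 1 probe set.

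On the lower side, Csf1r, the receptor for macrophage colony-stimulating factor, differed by -0.73 (SE 0.19), from 7.96 ± 0.17 to 7.23 ± 0.37 (SD, n = 3). Cd72, a co-receptor of B cells, differed by -0.77 (SE 0.20), and Ifi206, an interferon-inducible gene, by -0.83 (SE 0.14). Glipr1l1 had the largest difference at -1.29 (SE 0.30). The other log2 differences were -1.03 for the receptor gene P2ry10, -1.02 for Sugct, -0.997 for Ugt1a5, -0.98 for Msantd2, -0.81 for the glutamate receptor subunit Gria3, -0.76 for Ugt3a1, -0.76 for Tsacc and -0.76 for Calhm2. Of these 12 genes, 6 lay below the median gene level and 4 rested on 1 probe set. Among the 260 genes, 58 were predicted genes or olfactory or vomeronasal receptors and are only counted.

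Interferon-stimulated genes, the antiviral genes that cells switch on in response to interferons, were lower as a list in Dnmt3a+/- cells. Of 28 measured members, 27 had a negative log2 difference, with a median of -0.29, or a level about 18% lower. They included Oas2, a sensor of double-stranded RNA, at -0.55 (SE 0.12), the immunity-related GTPase Igtp at -0.49 (SE 0.14), Ifi44 at -0.43 (SE 0.12), Rtp4 at -0.76 (SE 0.24) and Irf9, a subunit of the factor that interferon receptors activate, at -0.47 (SE 0.16). Ifit3 (0.01, SE 0.54) and Bst2 (-0.02, SE 0.12) lay near 0. The list's median per array, relative to the wild-type mean of each gene, was 0.01 ± 0.03 in wild-type and -0.28 ± 0.02 in Dnmt3a+/- cells (SD, n = 3), with an exact permutation p of 0.1, the smallest possible. Camera placed the list below all other genes (adjusted p = 1.58e-09 over 26 lists, and adjusted p = 0.0468 with an estimated correlation), and fry gave an adjusted p of 0.00179. It was the only list that held with an estimated correlation. The preset correlation also gave this list low unadjusted p-values (camera) when arrays were regrouped 3 against 3 across genotypes. These went down to 9.72e-05, against 6.06e-11 for the genotypes. Such regroupings share the genotypes unequally between the groups and so keep part of any genotype difference. They therefore cannot show whether the preset p is calibrated for these arrays. Random lists matched on level had a median of -0.06, and the list lay at their percentile 0. Of the 6 other lists that passed, the progenitor list lay at percentile 0 of its matched lists (their median -0.08), the Polycomb list at 3.03 (-0.12), the leukaemia list at 5.38 (-0.11) and the neutrophil list at 100 (-0.07). The DNA methylation list lay at 18.5 (-0.09) and the ribosomal proteins at 75.7 (-0.11), well within the range of genes of similar level, and the leukaemia list was not clearly outside it. The random lists were drawn gene by gene, so a percentile overstates how unusual a list is where its members vary together. Estimated correlations were 0.554 for the neutrophil, 0.377 for the leukaemia and 0.236 for the progenitor list. Of the members, 0 passed over all genes and 1, Oas2, passed adjusted over the list alone (adjusted p = 0.049, limma), while 14 were non-overlapping and lower. With an estimated correlation the call was lost without any 1 of the arrays (adjusted p = 0.0992 to 0.233), while with the preset correlation it held each time. Leaving out an array also takes a residual degree of freedom from the estimated version. That loss therefore does not by itself show dependence on single arrays. The list's estimated correlation was -0.0217, below the preset 0.01, so correlated members did not raise its p.

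**Figure D3:**
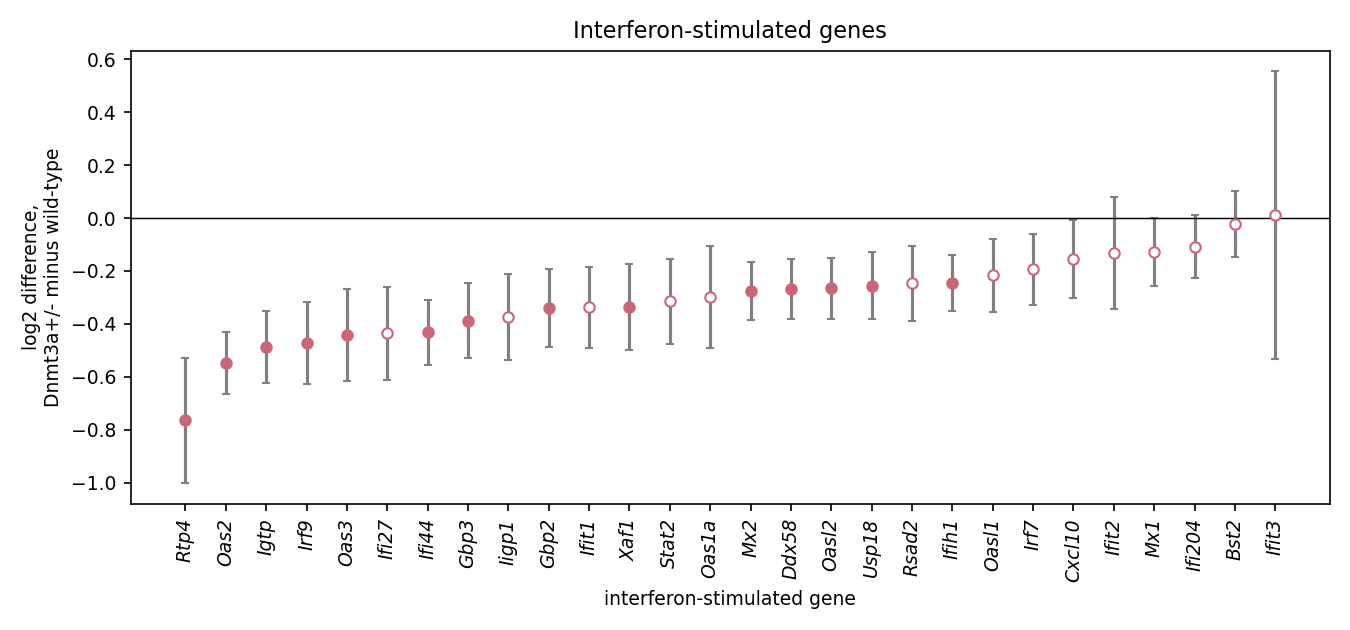
Log2 difference (Dnmt3a+/- minus wild-type) of the 28 measured interferon-stimulated genes with its SE, filled where the 3 arrays of one genotype do not overlap the other 3. The points run from -0.76 for Rtp4 to 0.01 for Ifit3, and 27 of 28 lie below 0.

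Genes of multipotent progenitors and early lymphoid priming were also lower as a list with the preset correlation. Of 18 measured members, 16 had negative differences, with a median of -0.24 (camera, adjusted p = 0.00898, but adjusted p = 0.827 with an estimated correlation). Notch1 differed by -0.39 (SE 0.12), the chromatin organiser Satb1 by -0.33 (SE 0.13) and Ikzf1, the lymphoid transcription factor Ikaros, by -0.29 (SE 0.12). The cytokine receptor Flt3 stood at -0.32 (SE 0.16) and Cd34 at -0.23 (SE 0.13). Of the members, 0 passed over all genes and 0 adjusted over the list alone. The call was lost after cyclic loess (median -0.12, adjusted p = 0.0522) and without Dnmt3a+/- replicate 1 (median -0.18, adjusted p = 0.27) or wild-type replicate 3 (median -0.19, adjusted p = 0.0527). In the arrays the medians were 0.00 ± 0.07 in wild-type and -0.24 ± 0.13 in Dnmt3a+/- cells (SD, n = 3).

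Long-term stem cell genes did not pass as a list (30 measured, median -0.05, camera adjusted p = 0.438), and the members with the smallest p were Tgm2 at 0.29 (SE 0.12), Ndn at -0.52 (SE 0.24) and Mycn at -0.25 (SE 0.14). The markers of the sort were close between genotypes, with Kit at -0.11 (SE 0.10) and Ly6a, which encodes Sca-1, at -0.02 (SE 0.13). Kit was nonetheless lower on every Dnmt3a+/- array than on any wild-type array, with a difference of -0.02 after cyclic loess, while Ly6a overlapped. Stem cell regulators discussed for Dnmt3a loss did not pass either (16 measured, median -0.13, adjusted p = 0.213), with Evi2a at -0.42 (SE 0.13) and Men1 at -0.22 (SE 0.11). Hox genes and their cofactors had a median of -0.04 over 20 members (adjusted p = 0.711), with Hoxb4 at -0.25 (SE 0.14), Hoxb9 at 0.20 (SE 0.12) and Hoxb5 at -0.27 (SE 0.18). For none of these 3 lists did a member pass, over all genes or adjusted over the list alone.

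Genes of the DNA methylation machinery, among them Dnmt3a itself, were lower as a list with the preset correlation (22 measured, 19 negative, median -0.13, camera adjusted p = 0.0245, but adjusted p = 0.827 with an estimated correlation). Tet2, which oxidises methylated cytosine and is often mutated in myeloid disease, differed by -0.44 (SE 0.16), Tet3 by -0.26 (SE 0.10) and Dnmt3b, the sister enzyme of Dnmt3a, by -0.34 (SE 0.14). The maintenance enzyme Dnmt1 differed by 0.07 (SE 0.18). Polycomb and histone methylation genes had 25 of 27 members on the negative side with a median of -0.19 (adjusted p = 0.000219, but adjusted p = 0.577 with an estimated correlation), including Kmt2c at -0.33 (SE 0.11), Kdm5b at -0.36 (SE 0.13) and Ehmt2 at -0.25 (SE 0.10). Counterparts of genes recurrently mutated in acute myeloid leukaemia had 26 of 28 on that side with a median of -0.16 (adjusted p = 0.00116, but adjusted p = 0.827 with an estimated correlation), with the kinase gene Jak2 at -0.40 (SE 0.11). By its definition the leukaemia list shares Tet2, Idh1 and Idh2 with the DNA methylation list and Ezh2, Asxl1, Kmt2a and Kdm6a with the Polycomb list. It also shares Flt3 with the progenitor list, so these calls are not independent. In each of these 3 lists 0 members passed over all genes and 0 adjusted over the list alone. After cyclic loess none of the 3 passed. The medians were then -0.07 for the Polycomb and -0.07 for the leukaemia list (adjusted p = 0.261 for both), and -0.12 for the DNA methylation list (adjusted p = 0.398), whose mean moved from -0.14 to -0.06. Without Dnmt3a+/- replicate 2, the array that stood apart, the leukaemia list had a median of -0.09 (adjusted p = 0.0758) and the DNA methylation list one of -0.04 (adjusted p = 0.374), while the Polycomb list passed with -0.14 (adjusted p = 0.00105). The DNA methylation call was also lost without wild-type replicate 2 (median -0.12, adjusted p = 0.085), with the filter at the 75th percentile (median -0.15, adjusted p = 0.0642), with the median of probe sets (median -0.12, adjusted p = 0.133) and with array weights (median -0.09, adjusted p = 0.1). With any 1 of the remaining arrays left out it held, with the largest shift without Dnmt3a+/- replicate 3 (median -0.21, adjusted p = 0.00849). A second quantile normalization ended all 3 calls, with medians of -0.13 for the DNA methylation (adjusted p = 0.239), -0.09 for the Polycomb (adjusted p = 0.0864) and -0.08 for the leukaemia list (adjusted p = 0.0999). The DNA methylation list was at -0.33 on Dnmt3a+/- replicate 2, and at -0.06 and -0.07 on the other Dnmt3a+/- arrays.

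Neutrophil genes were the only list past the threshold on the higher side (18 measured, 14 positive, median 0.19, camera adjusted p = 0.0245, but adjusted p = 0.827 with an estimated correlation). Retnlg (0.98) was the 1 member that passed adjusted over the list alone (adjusted p = 0.0386, limma), and Mmp8, a collagenase of neutrophil granules, differed by 0.64 (SE 0.20), while Fcnb stood at -0.26 (SE 0.14). The shift rested on single arrays: the medians were 0.66, 0.17 and 0.00 in Dnmt3a+/- and 0.13, -0.28 and 0.21 in wild-type cells. The call was lost after cyclic loess with a similar median (0.19, adjusted p = 0.0522) and without Dnmt3a+/- replicate 1 (median 0.01), and the sign turned without wild-type replicate 2 (median -0.0016). It held with larger medians without wild-type replicate 1 (0.31, adjusted p = 0.00948) or 3 (0.33, adjusted p = 0.000517). The same was true without Dnmt3a+/- replicate 2 (0.24, adjusted p = 0.00552) or 3 (0.34, adjusted p = 0.00277), and with array weights (0.48, adjusted p = 0.000126).

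Genes of other lineages that the sort should remove did not pass. Monocyte and macrophage genes had a median of 0.08 over 19 members (adjusted p = 0.831), with Csf1r at -0.73, Adgre1 at 0.42 (SE 0.15) and Vcam1 at 0.78 (SE 0.29). Myeloid regulators stood at -0.04 over 18 members (adjusted p = 0.456), with Cd33 at -0.46 (SE 0.15) and the transcription factor Irf8 at -0.47 (SE 0.18). The B lineage list had a median of 0.01 over 15 members (adjusted p = 0.432). Cd72 (-0.77) and Cd22 (0.51, SE 0.14) passed adjusted over that list alone in opposite directions (adjusted p = 0.05 for each, limma), and Cd79a stood at 0.85 (SE 0.33). T and NK genes had a median of 0.03 over 19 members (adjusted p = 0.438), with Klrd1 at -0.71 (SE 0.17), Cd3e at 0.33 (SE 0.12) and Ncr1 at 0.45 (SE 0.18). Erythroid genes stood at -0.05 over 15 members (adjusted p = 0.438), with Rhd at -0.33 (SE 0.11), the carbonic anhydrase Car1 at -0.78 (SE 0.28) and Ermap at -0.31 (SE 0.16). Megakaryocyte genes had a median of -0.03 over 19 members (adjusted p = 0.711), with Gp1bb at 0.33 (SE 0.14), F2rl2 at -0.45 (SE 0.20) and Gp6 at 0.26 (SE 0.12). Mast cell and basophil genes had one of 0.03 over 12 members (adjusted p = 0.527), with Mcpt8 at 0.45 (SE 0.16) and Cpa3 at -0.34 (SE 0.26). Stromal and endothelial genes had 16 of 19 members on the positive side and a median of 0.11 (adjusted p = 0.0963), with Adipoq at 0.33 (SE 0.13), Cxcl12 at -0.32 (SE 0.13) and Pecam1 at -0.24 (SE 0.12).

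Mitosis genes had a median of -0.16 over 27 members (adjusted p = 0.0963), but medians per array overlapped widely, from -0.36 to 0.21 in wild-type and from -0.45 to 0.06 in Dnmt3a+/- cells. Cdc20 stood at -0.43 (SE 0.24), Prc1 at -0.30 (SE 0.21) and Cenpa at -0.16 (SE 0.12). DNA replication genes had a median of -0.07 over 26 members (adjusted p = 0.957), with Cdt1 at 0.17 (SE 0.10), Gins1 at -0.33 (SE 0.26) and Rfc4 at -0.22 (SE 0.19). Cyclin-dependent kinase inhibitors and quiescence genes had 16 of 19 members on the negative side with a median of -0.12 (adjusted p = 0.062), and their medians per array did not overlap between genotypes as deposited (0.00 ± 0.05 in wild-type and -0.18 ± 0.03 in Dnmt3a+/- cells, SD). After cyclic loess they overlapped (-0.06 to 0.06 in wild-type and -0.10 to 0.00 in Dnmt3a+/- cells, list adjusted p = 0.398). They included Tob1, an inhibitor of proliferation, at -0.51 (SE 0.15), Rb1 at -0.27 (SE 0.15) and Rbl2 at -0.18 (SE 0.10). Targets of p53 stood at -0.04 over 21 members (adjusted p = 0.487), with Trp53inp1 at -0.44 (SE 0.15), Polk at -0.37 (SE 0.13) and Fas at 0.27 (SE 0.12). Immediate early genes, which respond to handling, had a median of -0.12 over 27 members (adjusted p = 0.438), with Klf4 at 0.33 (SE 0.15), Ier5 at -0.30 (SE 0.13) and Btg2 at -0.58 (SE 0.33).

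Genes that DNA methylation silences or marks by parent of origin did not pass as lists. Imprinted genes had a median of 0.06 over 27 members (adjusted p = 0.438), with Dlk1 at 0.26 (SE 0.10) and the non-coding Rian at 0.22 (SE 0.11). Germ cell genes that are methylated in other tissues had a median of 0.06 over 22 members, 16 of them positive (adjusted p = 0.131), with Ddx4 at -0.37 (SE 0.15), Sycp3 at -0.42 (SE 0.20) and Stk31 at 0.28 (SE 0.14). Ribosomal protein genes had 56 of 66 members on the negative side and a median of -0.09 (camera, adjusted p = 0.0274, but adjusted p = 0.827 with an estimated correlation). That median was no lower than that of random lists of similar level (-0.11), and after cyclic loess it was -0.03 (adjusted p = 0.669). The call was also lost without wild-type replicate 2 (median -0.07, adjusted p = 0.085) or 3 (median -0.10, adjusted p = 0.0527). It was lost without Dnmt3a+/- replicate 1 (median -0.09, adjusted p = 0.29) or 2 (median -0.06, adjusted p = 0.27). The call held without wild-type replicate 1 (median -0.11, adjusted p = 0.0257) or Dnmt3a+/- replicate 3 (median -0.14, adjusted p = 0.000595). It was lost as well with the filter at the 75th percentile (median -0.08, adjusted p = 0.0765), the median of probe sets (median -0.08, adjusted p = 0.133) and a second quantile normalization (median -0.03, adjusted p = 0.633). The members with the smallest p were Rps7 at -0.45 (SE 0.20), Rpl5 at -0.29 (SE 0.14) and Rpl3l at -0.37 (SE 0.18). Oxidative phosphorylation genes had a median of -0.07 over 74 members (adjusted p = 0.122), which turned to 0.04 after cyclic loess, with Ndufb4 at -0.52 (SE 0.12), Atp5e at -0.51 (SE 0.13) and Cox7a2l at -0.32 (SE 0.12). Median, mean and camera differed in sign for the Hox, monocyte, megakaryocyte, T and NK, DNA replication and imprinted lists, none of which passed.

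**Figure D4:**
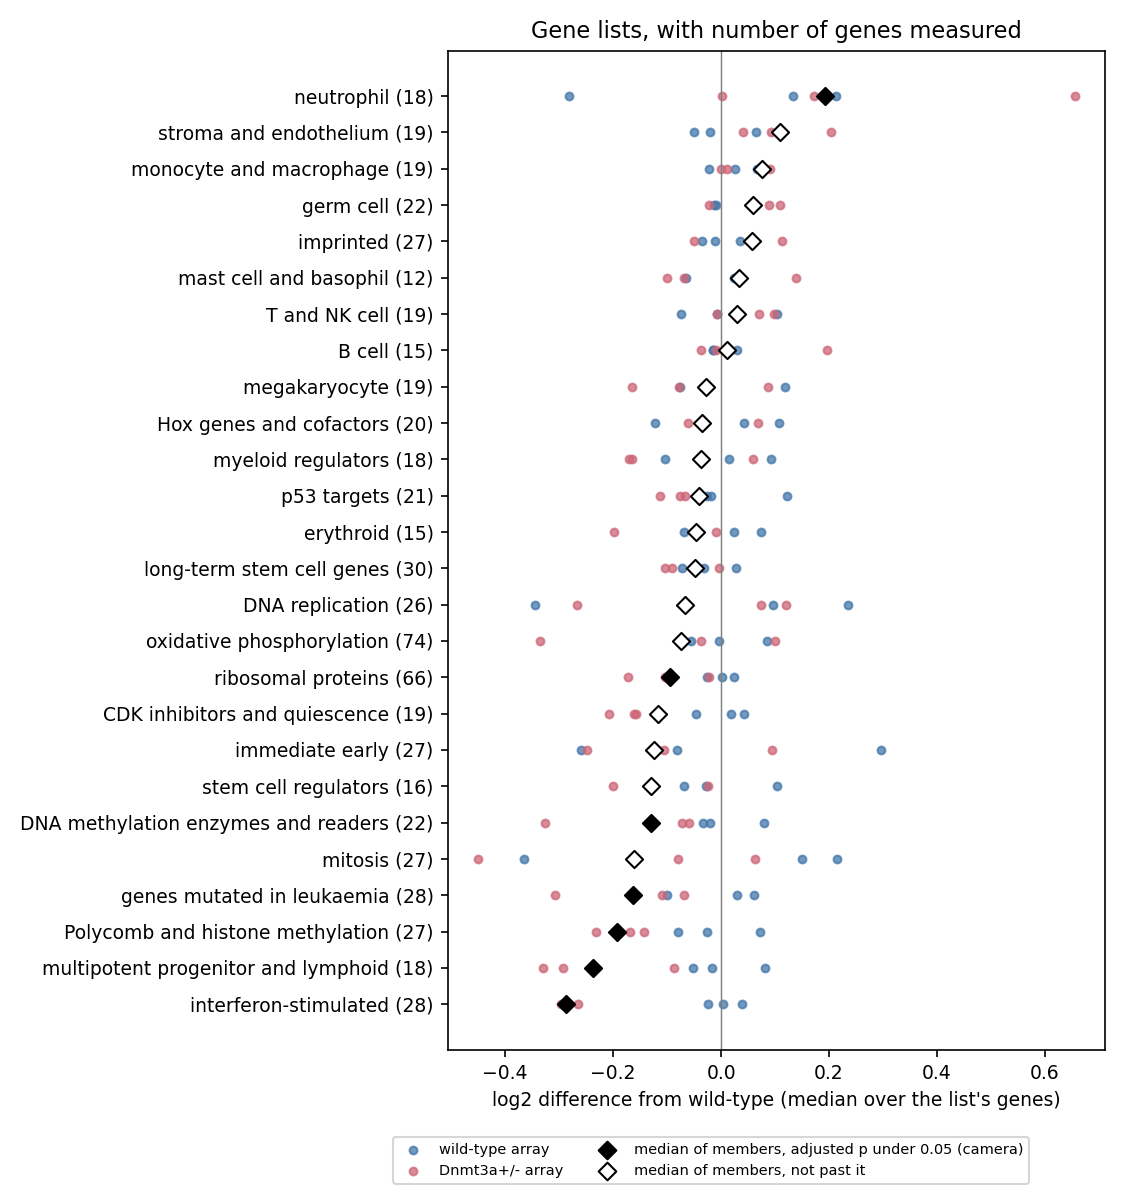
Median log2 difference of the 26 gene lists (diamonds, filled where camera gave an adjusted p under 0.05 with the preset correlation) and the median of each array relative to the wild-type mean of each gene (small points), with the number of genes measured. The interferon-stimulated list lies lowest at -0.29, with the Dnmt3a+/- arrays between -0.30 and -0.27, and the neutrophil list lies highest at 0.19, with widely spread arrays.

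Genes near Dnmt3a were compared with the rest because a targeted allele can carry neighbouring sequence of another strain. Of the 59 measured genes within 10 Mb of Dnmt3a in the RefSeq table of GRCm38.p6, leaving out Dnmt3a, 0 had an unadjusted p under 0.01, which allows a share of up to 5.08%. Of the other 20000 genes 260 did, or 1.3% (Fisher's exact test, two-sided, p = 1). At unadjusted p under 0.05 there were 3 such genes near Dnmt3a (Fisher's exact test, p = 0.625).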

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

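All alternatives except one were chosen before the data were examined; cyclic loess together with leaving out Dnmt3a+/- replicate 2 was added afterwards. Dnmt3a stayed lower in every alternative run, at -0.17 after cyclic loess to -0.37 without Dnmt3a+/- replicate 1 (-0.24 without wild-type replicate 2), and never passed over all genes. No gene and no probe set passed adjusted p 0.05 in any alternative, and no gene passed 0.10 in the fit as planned; the smallest adjusted p over genes was 0.0528, without a filter. Of the Dnmt3a probe sets, 4 passed over Dnmt3a alone with a variance trend and robust estimation, and 0 otherwise. Genes at unadjusted p under 0.01 numbered 613 with array weights and 128 to 338 when single arrays were left out (128 without wild-type replicate 2, 154 without wild-type replicate 3). Genes apart by 1.5-fold numbered 276 with the median of probe sets (119 higher and 157 lower), 29 at 2-fold and 179 to 473 when single arrays were left out (473 without Dnmt3a+/- replicate 1, 179 without Dnmt3a+/- replicate 2); a variance model or block does not enter that count. The 7 lists became 5 with the filter at the 75th percentile or the median of probe sets (DNA methylation and ribosomal proteins lost in both), 3 after a second quantile normalization and 1 after cyclic loess, with an estimated correlation or with fry, and 4 to 12 when single arrays were left out (12 without wild-type replicate 1, 4 without Dnmt3a+/- replicate 1, 11 without Dnmt3a+/- replicate 3). The interferon list passed in each of these. For genes near Dnmt3a, 0 to 2 had an unadjusted p under 0.01 when single arrays were left out and 2 with array weights, and Fisher's exact test found no difference in any alternative. The neutrophil median turned to -0.0016 without wild-type replicate 2 and was 0.343 without Dnmt3a+/- replicate 3. With the added setting 6 lists passed with the preset correlation: the interferon list, the lymphoid priming (adjusted p = 0.00955), neutrophil (0.011) and Polycomb (0.0255) lists, which cyclic loess alone had ended, and 2 others. The medians turned to 0.0103 for DNA methylation, which did not pass, and to 0.145 for DNA replication and 0.0708 for oxidative phosphorylation genes, which passed on the higher side (adjusted p = 0.0194 for both); an estimated correlation was not run in that setting, and as deposited it gave these 2 lists adjusted p = 0.988 and 0.834. Apart from the fewer arrays or the altered threshold, the cause of these changes was not tested.

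The shared replicate numbers did not pair the arrays: deviations of same-numbered arrays from their genotype means correlated at -0.0475, -0.091 and 0.113 across genes, and only replicate 3 correlated best with its own number. With the replicate number as a block, Dnmt3a stood at -0.31 (adjusted p = 0.714), 0 genes, 0 probe sets and 0 Dnmt3a probe sets passed, 216 genes had an unadjusted p under 0.01, 0 of them near Dnmt3a, and 8 lists passed. Over all alternatives, 383 of 442 list values stayed on their side of the threshold, 39 lost it, 16 gained it and 4 reversed; the sign of a median changed in 48 values from 17 lists, most of them not called. Single named genes changed sign in 19 of 1514 values, none past a threshold. Signal over background limits dim genes, and 3 arrays per genotype limit all comparisons.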

Other observations

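The families, the tests of probe sets within a gene, the test of the trend with level and the other splits, except those of genes at unadjusted p under 0.01, were chosen after the data were examined, as were the explanations, while cyclic loess and leaving out single arrays were planned. Grouping genes by the stem of their symbol gave 334 families of at least 8 genes, of which 34 passed camera with the preset correlation and 0 with an estimated one. With few residual degrees of freedom and 334 families to adjust over, the estimated version had little power, so its 0 decides little. Those that passed as deposited, after cyclic loess and without Dnmt3a+/- replicate 2 numbered 3, all higher in Dnmt3a+/- cells: the vomeronasal receptors (Vmn, 91 genes, median 0.17, adjusted p = 3.38e-06), the kallikreins (Klk, 23 genes, median 0.18, adjusted p = 0.000442) and the Speer genes of the testis (9 genes, median 0.41, adjusted p = 0.00517). Their mean levels were low (6.93, 7.21 and 7.25), and dim genes on average lay higher on Dnmt3a+/- arrays. Families were not compared with random genes of similar level, so their shift was not separated from that trend. Olfactory receptors (Olfr, 383 genes, mean level 6.77) also lay higher as deposited (adjusted p = 0.000126) but did not pass after cyclic loess (adjusted p = 0.126). On the lower side, Cep genes of the centrosome (34 genes, median -0.20) and Ddx RNA helicases (35 genes, median -0.215) passed as deposited and after cyclic loess, but not without Dnmt3a+/- replicate 2 (adjusted p = 0.0617 and 0.0903). Genes with the stem Irf, which include but are not limited to the interferon regulatory factors, also lay lower (11 genes, median -0.25, adjusted p = 0.00752, and 0.0713 after cyclic loess). So did Ifi genes (14 genes, median -0.20, adjusted p = 0.0148, and 0.0542 after cyclic loess). Both passed without Dnmt3a+/- replicate 2 (adjusted p = 0.0305 and 0.00666), and both share members with the interferon list. Other interferon-related families did not pass as deposited. They were Oas (10 genes, median -0.20, adjusted p = 0.218), Slfn (10 genes, median -0.165, adjusted p = 0.192) and Gbp (9 genes, median -0.22, adjusted p = 0.896). For Gbp camera gave the direction as higher.

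A test of unequal differences among the probe sets of a gene (diffSplice in limma) passed for 19 of 17969 genes, and for 5 of 13820 above the stricter filter. Gm4759 led (42 probe sets, adjusted p = 2.65e-15), followed by the splicing factor gene Cwc22 (70 probe sets, adjusted p = 7.86e-06), Rgr (6 probe sets, adjusted p = 0.00438) and the potassium channel gene Kcnma1 (17 probe sets, adjusted p = 0.0063). The mean over all probe sets of Gm4759 differed by 0.07 (SE 0.12) and that of Cwc22 by -0.25 (SE 0.13).

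The lower interferon-stimulated genes are the pattern that held in the most settings. A signal-dependent trend between arrays, as the whole cause, is argued against by the median of -0.231 after cyclic loess, where the arrays stayed apart (0.00 ± 0.05 in wild-type against -0.25 ± 0.04 in Dnmt3a+/- cells, SD, n = 3) and camera gave an adjusted p of 1.61e-09. An effect of Dnmt3a+/- replicate 2 alone is argued against by the median of -0.3 without it (adjusted p = 1.02e-11 with the preset correlation), although with an estimated correlation the call was lost without it (adjusted p = 0.0992) and without each other array. Fewer arrays also leave the estimated version fewer degrees of freedom. The 10 splits of the 6 arrays are too few for a share under 0.05: the real split alone (1 of 10) gave a median of this size, 0.287, and the highest of the others was 0.148. Camera with the preset correlation gave the list an unadjusted p under 0.05 also in splits that mixed the genotypes, down to 9.72e-05. Such splits keep part of any genotype difference, so they do not show what arrays without one would give. Animals that differed in exposure or genetic background, and the genotype itself, may each be the source and were not tested.

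Dim genes lay higher and bright genes lower on average in Dnmt3a+/- arrays. A candidate explanation is that 1 array carries the trend. The median of the brightest minus that of the dimmest 10% of genes was -0.424 on Dnmt3a+/- replicate 2. The mean of the other Dnmt3a+/- arrays, -0.0847, lay within the range of the wild-type arrays (-0.102 to 0.0505). Dnmt3a+/- replicate 1 alone, at -0.144, lay below that range, and the correlation across genes of level and difference was -0.369 with all arrays and -0.22 without replicate 2. Whether 1 array accounts for the trend therefore stays open. Whether replicate 2 differs by its RNA or by its cells was not tested.

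The Dnmt3a probe sets had differences from -1.04 to 0.66. An equal change over all of them was tested by the F test of diffSplice (unadjusted p = 0.0204, and adjusted p = 0.65 over all genes). The F test also gave an unadjusted p of 0.025 after cyclic loess. Without Dnmt3a+/- replicate 1, 2 or 3 it gave 0.0251, 0.0287 and 0.00727, but without wild-type replicate 1, 2 or 3 it gave 0.0737, 0.0989 and 0.124. An equal change therefore stays open. Dim probe sets that cannot fall were weighed by the same F test over the probe sets above the 75th percentile, which gave an unadjusted p of 0.0146 (adjusted p = 0.802 over all genes). This F test gave 0.00421 without Dnmt3a+/- replicate 1 and 0.000223 without replicate 3, but 0.14 without replicate 2. Without wild-type replicate 1, 2 or 3 it gave 0.155, 0.158 and 0.0723, so this test does not settle whether the brighter probe sets differ unequally. Of the 14 probe sets with a mean level above 9 (median of all probe sets 5.89), 7 lay below -0.5 and 7 above -0.3. The latter were bright and did not clearly fall, which argues against dim probe sets as the whole source of the unequal differences. A disrupted allele that still gives RNA from part of the gene may be the source, but without positions of the probe sets it was not tested.

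The 10 splits of the 6 arrays are too few for a share under 0.05, so for the counts only the real value and the highest other are given. At unadjusted p under 0.01, 2 of 10 splits gave at least the real 260 genes, with 324 as the highest other. For genes apart by 1.5-fold 2 of 10 gave at least 174, with 191 as the highest other, and for gene lists 3 of 10 gave at least 7, with 15 as the highest other. These highest counts came from the split of wild-type replicate 1 with Dnmt3a+/- replicates 1 and 2 against the rest, a structure of the arrays that does not follow genotype. Where the real count was 0, all 10 splits reach it by definition, so that share says nothing. The highest other count was 1 for genes past adjusted p 0.05, 0 for probe sets and 1 for genes near Dnmt3a.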
